A study of Bos taurus with 32 samples.

How the data were processed

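Liver and skeletal muscle biopsies were taken by percutaneous punch from 16 calves at about 4 months of age, and poly(A) RNA was sequenced from 32 libraries. Per the labels' protocols, libraries were made with a stranded TruSeq mRNA kit and read as 100-base pairs on a NovaSeq instrument. FastQC 0.11.9, Trimmomatic, STAR 2.7.0b and featureCounts of Subread 2.0.3 were used, per the submitters' processing notes. The genome build, the annotation and the settings for strand and for reads with several matches are not given in the sources used here. Genes that share reads with close copies (PGK1, ATP5F1B, RPLP0, PSAP and the BOLA genes) and overlapping genes are therefore uncertain. No gene coordinates are printed, because the build is not given.

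The deposited values are whole-number estimated counts per Entrez gene, 1 table per tissue, not scaled to library size. Their pattern is that of an adjustment between sets of libraries within each tissue and sex before they were deposited, a step that no label names. In genes at 0 throughout a set of libraries, where no adjustment between sets can be fitted, even values from 2 to below 30 were in excess over other genes. The excess was 41.2 percentage points in liver males, 43.1 in liver females, 44.2 in muscle males and 47.9 in muscle females. The sets are those with the largest excess among 127 splits in each tissue and sex, where values dealt to other genes gave at most 3.55 and the second set 34.0 to 44.1. In 3 of the 4 the set is 1 library alone, a stand-in library as defined below. In muscle males it is AI male 1 with IVP males 2, 3 and 4, which nearly follows origin, so that this set as a covariate takes away most of the contrast between origins. Tests had been fixed for raw counts before the data were examined. Because the values were already whole, rounding changed nothing, and edgeR was kept as the main test. An adjustment of this kind can shrink the spread within groups, and p-values cannot take account of that.

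In 3 libraries the counts lay closer to the mean of their group mates than counting noise allows. The squared distance, over genes with 20 to below 200 counts, was 0.0337 times counting noise in liver AI female 4, 0.0817 times in liver IVP male 2 and 0.0445 times in muscle AI female 2. In all other libraries it was 3.79 to 14.5 times. These 3 libraries are called stand-in libraries here. They entered the fits as designed, but were not counted as independent samples. All means ± SD are over independent libraries, with n = 3 in liver AI females, liver IVP males and muscle AI females and n = 4 in the other groups. Muscle AI male 1 and IVP male 1 deviate from their groups together (correlation 0.902 across genes), so the 8 muscle males are not fully independent. Genes counted in a stand-in library and at 0 in all its group mates numbered 817, 246 and 504 in these libraries, in the same order. Each count of changed genes was also recomputed without these libraries and genes, an alternative chosen after seeing the data.

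Symbols came from a RefSeq gene table, by Entrez number. Of 35092 genes listed, 31630 (90.1%) had a symbol. The other 3462 held 1.43% of liver and 0.733% of muscle counts and stayed in the tests. Total counts per library ran, in units of 1e6, from 23.69 to 40.23 in liver and from 34.98 to 40.37 in muscle. Floors for a group at 0 are taken at 3 counts per library and cover counting error only.

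The 16 libraries of a tissue were fitted together as 4 groups (origin by sex) with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1. Genes were kept by filterByExpr, libraries scaled by TMM, and differences tested with the robust quasi-likelihood test and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 were called. The contrasts were IVP minus AI in males, in females and over both sexes, the male minus the female difference (the sex by origin interaction), and males minus females. Log2 differences carry the standard error from the test. Levels are CPM (counts per 1e6 counts), computed here with TMM-scaled library sizes.

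Gene lists, 43 in all, were fixed before the data were examined. In each tissue 42 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The same test with an estimated correlation and the rotation test fry were run beside it. Of the 420 list tests, 105 passed, and 3 passed with an estimated correlation. These were the X-linked list in both tissues and the imprinted list in liver, all between the sexes, where XIST is a member. Each list's called members are given over all genes tested and adjusted over the list alone.

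Named genes were set by a rule. For each contrast within a sex these are the up to 8 called genes per direction with the smallest adjusted p, a symbol and a mean of at least 1 CPM. Up to 12 called list members follow. For the contrasts over both sexes and the interaction the numbers are 6 and 6, and between the sexes 5 per direction plus XIST. For each list that passes, up to 3 members with the smallest p in its direction are named. Some genes that the rule names are not reported here.

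The code was tested on simulated counts with 200 genes changed, for IVP minus AI in females. In liver, 46.3% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 95.5% of those changed 4-fold were called in the right direction, among 17050 genes. In muscle the shares were 17.9%, 50.7% and 93.9%, among 15460 genes. Of the calls, 5.14% in liver and 2.61% in muscle fell on unchanged genes. With no change simulated, 4.46% of liver and 4.40% of muscle genes had an unadjusted p under 0.05. With 1 library set at the mean of its group mates the shares were 7.26% and 7.41%.

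Alternatives fixed in advance were RLE size factors, no filter or a strict filter on low counts (1 CPM in 4 libraries), the edgeR likelihood ratio test, limma voom with sample weights, DESeq2 1.42.0, 1 surrogate variable (sva 3.50.0), age as a covariate, the replicate number as a block, only the 8 libraries compared, and leaving out each library. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Blood samples that the protocol text mentions were not analysed here.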

Results

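Poly(A) RNA was measured in liver and skeletal muscle biopsies of dairy calves (Bos taurus) aged 114 to 143 days. The calves were born after timed artificial insemination with frozen-thawed semen (AI, 8 calves) or after transfer of a single frozen-thawed embryo that had been produced in vitro (IVP, 8 calves). Each origin held 4 males and 4 females, and each calf gave 1 liver and 1 muscle library, which makes 8 groups of 4. Samples of both tissues with the same origin, sex, number and age were taken as the same calf. No group stood apart in total counts. Values are CPM ± SD over independent libraries and log2 differences ± SE. Adjusted p-values (Benjamini-Hochberg) come from the edgeR quasi-likelihood test for genes and from camera for gene lists. The comparisons ask whether conception in vitro goes with a different transcriptome at 4 months, in each tissue and each sex.

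AI females stood apart from the other groups in both tissues. On the first component of liver expression (42.4% of the variance), AI females averaged -23.5, against 13.1 in IVP females, 0.279 in AI males and 5.71 in IVP males. In muscle the first component (41.0%) averaged 24.2 in AI females, 4.76 in IVP females, -3.01 in AI males and -19.9 in IVP males. Transcripts encoded in the mitochondrial genome made up 9.92% of liver counts in AI females, 4.43% in IVP females, 5.44% in AI males and 5.60% in IVP males. In muscle the 10 most abundant genes took 22.5% of counts in AI females and 29.1%, 28.7% and 29.4% in IVP females, AI males and IVP males.

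**Figure D1:**
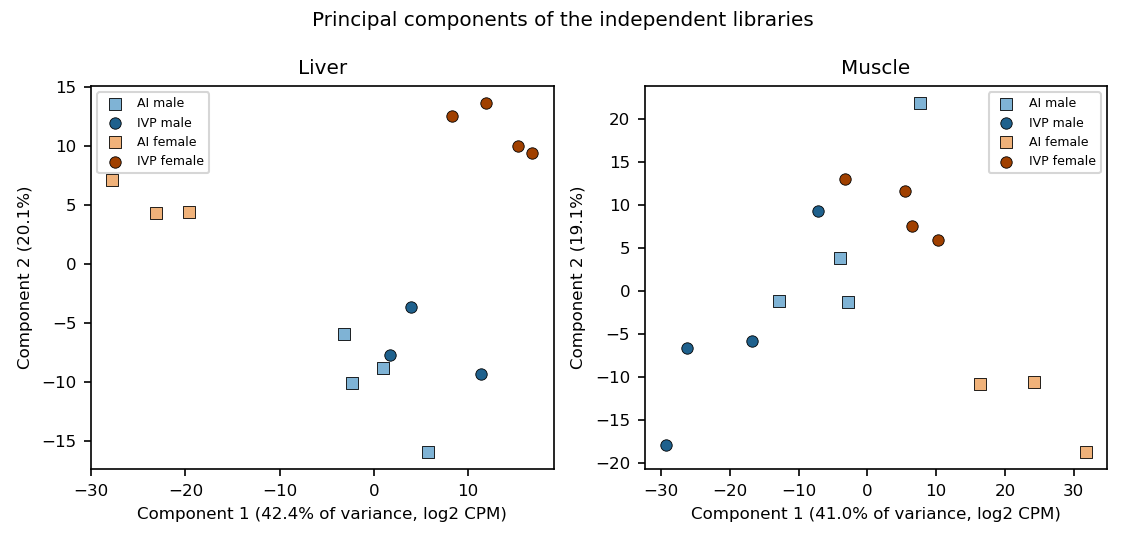
Scores of the independent libraries on the first and second principal components of log2 CPM (scores on both axes) in liver and in muscle, 1 point per library, with colours and markers for the 4 groups of origin and sex. Liver AI females lie at -27.8 to -19.7 on the first component, below all other liver libraries, and muscle AI females at 16.4 to 31.8, above all other muscle libraries.

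In the liver of male calves, IVP and AI animals differed in 182 of 17337 genes tested, 105 higher and 77 lower in IVP calves. SULT1B1 (Entrez gene 521920), a cytosolic sulfotransferase, rose from 17.2 ± 3.30 CPM (n = 4) to 28.5 ± 1.65 CPM (n = 3), a log2 difference of 0.73 ± 0.11 with an adjusted p of 0.00958. MMP14, a membrane-bound protease of the extracellular matrix, rose by 1.28 ± 0.20, and CAVIN2, a coat protein of caveolae, by 0.74 ± 0.12. SPPL2A (0.46 ± 0.073), VMA21 (0.51 ± 0.081), RTN4 (0.53 ± 0.085), AOC3 (0.50 ± 0.083) and ADAMTS1 (0.60 ± 0.10) were the other leading genes that rose. CRB1, a cell polarity protein, went from 13.3 ± 2.63 to 6.40 ± 0.698 CPM (-1.06 ± 0.16, adjusted p = 0.00958). ENTPD4 (-0.47 ± 0.082), ACTR8 (-0.75 ± 0.13), the cytochrome P450 gene CYP4A59 (-0.57 ± 0.10), MYT1L (-1.91 ± 0.35), NDUFAF8 (-0.61 ± 0.11) and RABEPK (-0.55 ± 0.10) were lower as well. ALPK2 was at 0 in the 3 independent IVP male libraries and at least 29.1-fold lower than in AI males, but was counted in stand-in library IVP male 2.

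In liver males 4 lists passed, and none with fry. The stellate cell, fibroblast and matrix list had a median log2 difference of 0.20 (adjusted p = 0.00411, or 0.978 with estimated correlation). None of its 31 members was called over all genes, by edgeR, and 4 passed when adjusted over the list alone. The matrix protein RELN stood at 0.41 ± 0.099, and the growth factor receptors PDGFRB and PDGFRA at 0.47 ± 0.13 and 0.49 ± 0.14. Of 26 endothelial markers (median 0.10, adjusted p = 0.0196, or 0.978 with estimated correlation), 1 was called and 4 passed adjusted over the list alone. KDR, a receptor for vascular growth factor, rose by 0.49 ± 0.10, while PECAM1 (0.31 ± 0.076) and ESAM (0.35 ± 0.095) missed the threshold. Nuclear genes of oxidative phosphorylation tested lower (median -0.13, adjusted p = 5.45e-06, or 0.978 with estimated correlation): 2 fell and 1 rose, against 6 and 2 adjusted over the list alone. NDUFA3 stood at -0.45 ± 0.094 and UQCR10 at -0.34 ± 0.079, and the gene that rose was ATP5F1B (0.75 ± 0.17). Ribosomal protein genes had a median of -0.20 (adjusted p = 2.72e-11, or 0.978 with estimated correlation). None of the 78 was called by edgeR, over all genes or adjusted over the list alone; RPLP1 stood at -0.39 ± 0.10, RPS10 at -0.32 ± 0.087 and FAU at -0.29 ± 0.080.

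Other list members called in liver males were the receptors NGFR (0.44 ± 0.087) and IL6R (0.58 ± 0.12) and the class II gene BOLA-DMA (0.51 ± 0.10). Lower were the cholangiocyte keratin KRT19 (-1.01 ± 0.21), the nuclear receptor NR1I2 (-0.40 ± 0.086), the B cell factor SPIB (-0.97 ± 0.21), BOLA-DOB (-0.83 ± 0.18) and GPT (-1.10 ± 0.25), an alanine aminotransferase. Without stand-in library IVP male 2, 1 gene was called, with differences of 0.73 for SULT1B1 and 1.28 for MMP14 (adjusted p = 0.106), and without the stand-in libraries and their genes 0 by edgeR (1653 at an unadjusted p under 0.05), against 2802 at that level, 3027 called by voom and 627 by DESeq2 with all libraries. Leaving out IVP male 1, 3 or 4, or AI male 1 or 2, gave 103, 64, 16, 32 and 77, and only the 8 male libraries 4.

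In the liver of female calves, 8113 of 17337 genes differed (46.8%), 4232 higher and 3881 lower in IVP calves, and 1966 by over 2-fold. PROS1 (Entrez gene 282006), the anticoagulant protein S, rose from 135 ± 9.56 CPM (n = 3) in AI females to 426 ± 34.1 CPM (n = 4) in IVP females, a log2 difference of 1.66 ± 0.088 (adjusted p = 1.40e-09). The translation initiation factor EIF4H rose by 2.02 ± 0.11, the lysosomal proteins LAPTM4A, NPC2 and PSAP by 1.39 ± 0.082, 1.33 ± 0.083 and 2.79 ± 0.17, and PPIB, a folding enzyme of the endoplasmic reticulum, by 1.48 ± 0.093. SCCPDH (1.26 ± 0.077) and SERBP1 (1.11 ± 0.071) followed. FAM193B (-1.20 ± 0.073), the methyltransferase SETD6 (-1.26 ± 0.078), ATP8B3 (-1.69 ± 0.11), CHRD (-1.52 ± 0.098), an inhibitor of bone morphogenetic proteins, and the mitotic kinesin KIF23 (-1.59 ± 0.11) fell, as did ATP2C2 (-1.14 ± 0.078), WWP2 (-1.18 ± 0.081) and the topoisomerase TOP3A (-0.93 ± 0.064).

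Lists of macrophages, T and NK cells and antigen presentation tested higher in the liver of IVP females. Interferon (median 0.73, adjusted p = 0.0642), B and plasma cell (0.46, 0.171), acute phase (0.24, 0.0642) and neutrophil lists (0.12, 0.709) did not pass. Of 24 macrophage and Kupffer cell markers, 17 rose and 1 fell, the same adjusted over the list alone (median 0.89, adjusted p = 1.44e-10, or 0.821 with estimated correlation). CTSS, a lysosomal protease, went from 52.8 ± 0.875 to 204 ± 21.2 CPM (1.94 ± 0.13), and the complement chains C1QC and C1QA rose by 1.87 ± 0.14 and 1.5 ± 0.13. The mannose receptor MRC1 rose by 1.24 ± 0.11. Of 34 T and NK cell markers, 22 rose and 1 fell (23 and 1 adjusted over the list alone; median 0.56, adjusted p = 9.58e-05, or 0.821 with estimated correlation). CD3D (1.85 ± 0.18) and CD3G (1.62 ± 0.17), chains of the T cell receptor complex, and PRF1 (1.60 ± 0.18), the pore-forming protein of killer cells, were among them. Of 22 genes of antigen presentation 11 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.00361, or 0.821 with estimated correlation), with BOLA-DRB3 at 1.48 ± 0.15, BOLA-DMA at 1.04 ± 0.11 and BOLA-DRA at 1.28 ± 0.14.

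Lists of hepatocytes and protein folding tested higher in the same livers. Of 26 hepatocyte markers 17 rose and 2 fell (17 and 3 adjusted over the list alone; median 0.55, adjusted p = 0.000255, or 0.821 with estimated correlation). ALB, serum albumin, stood at 21460 ± 1777 CPM in AI females and 43700 ± 4602 CPM in IVP females (1.02 ± 0.12), against 39520 ± 5273 and 46910 ± 5338 CPM in AI and IVP males. The retinol carrier RBP4 (1.28 ± 0.14) and plasminogen, PLG (0.78 ± 0.096), also rose. Of 29 genes of the unfolded protein and integrated stress response 17 rose and 5 fell, the same adjusted over the list alone (median 0.72, adjusted p = 0.00172, or 0.828 with estimated correlation). DNAJB9 (1.78 ± 0.17), EDEM1 (1.38 ± 0.15) and DNAJC3 (0.69 ± 0.082) work in the endoplasmic reticulum. Of 24 heat shock genes 12 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0408, or 0.828 with estimated correlation), with the chaperones HSPD1 at 1.04 ± 0.089, HSP90AA1 at 1.07 ± 0.13 and DNAJA1 at 1.17 ± 0.14. IL6R (1.51 ± 0.12), the endothelial cadherin CDH5 (1.65 ± 0.15), IGFBP3 (1.08 ± 0.099), which binds insulin-like growth factors, and RPLP0 (1.31 ± 0.10) rose too.

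Mitochondrially encoded and ribosomal protein genes tested lower in IVP females. Of 13 mitochondrially encoded genes 12 fell, the same adjusted over the list alone (median -1.09, adjusted p = 1.44e-10, or 0.821 with estimated correlation). COX3, a subunit of cytochrome oxidase, went from 15320 ± 1072 to 5283 ± 767 CPM (-1.54 ± 0.14), against 7401 ± 1251 and 7303 ± 1202 CPM in AI and IVP males, and COX2 and ND1 stood at -1.21 ± 0.10 and -1.21 ± 0.14. Of 78 ribosomal protein genes 43 fell and 4 rose, the same adjusted over the list alone (median -0.37, adjusted p = 1.98e-05, or 0.828 with estimated correlation). RPL38 stood at -1.26 ± 0.13, RPS28 at -0.97 ± 0.097 and RPS13 at -0.91 ± 0.11, and ATP5ME, a subunit of ATP synthase, at -1.26 ± 0.10. AI females were also the liver group that stood apart on the first component and in the mitochondrial share of counts.

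**Figure D2:**
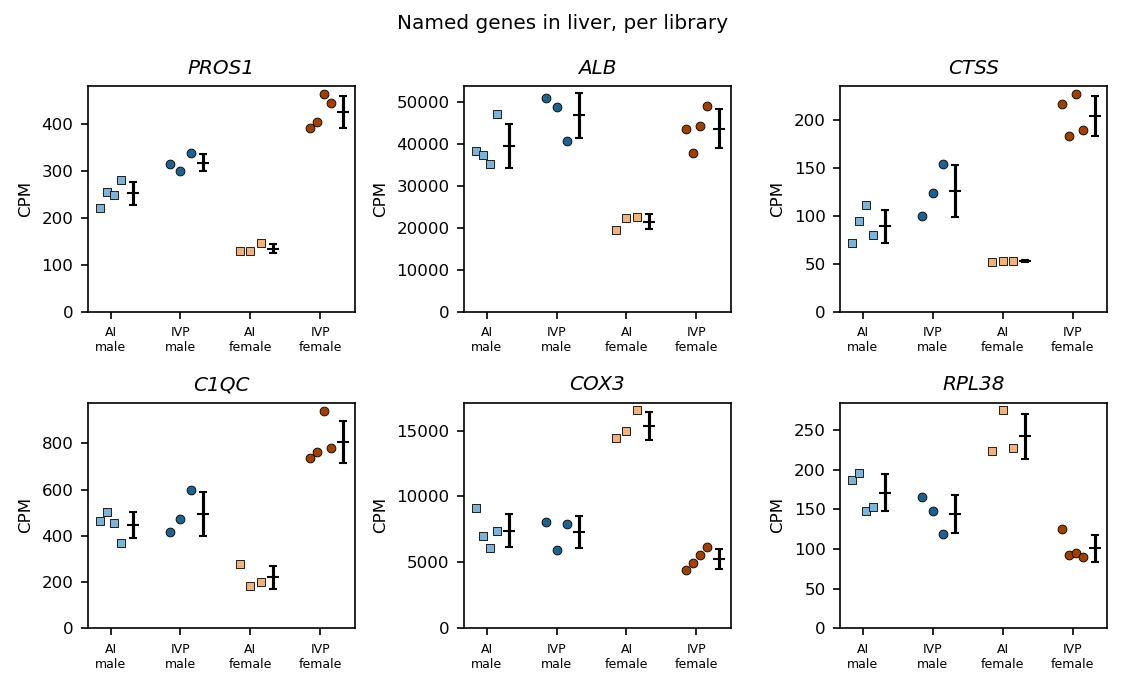
Levels of PROS1, ALB, CTSS, C1QC, COX3 and RPL38 in liver (CPM, vertical axis) by origin and sex (horizontal axis), with 1 point per independent library and a black bar for the mean ± SD. AI females lie apart from the other 3 groups, for example 52.8 ± 0.875 CPM of CTSS against 204 ± 21.2 in IVP females.

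Averaged over both sexes, 6835 liver genes differed, 3492 higher and 3343 lower in IVP calves. EIF4H (1.22 ± 0.074), PROS1 (0.99 ± 0.061), RTN4 (0.91 ± 0.061), SCCPDH (0.81 ± 0.054), the integrin ITGB1 (1.07 ± 0.074) and the collectin COLEC10 (1.01 ± 0.071) rose. FAM193B (-0.74 ± 0.052), ATP8B3 (-0.95 ± 0.074), ATP2C2 (-0.69 ± 0.055), SETD6 (-0.68 ± 0.055), the cytokine subunit IL23A (-0.83 ± 0.068) and TOP3A (-0.55 ± 0.045) fell. Of 24 macrophage markers 17 rose and 1 fell, the same adjusted over the list alone (adjusted p = 4.92e-09, or 0.780 with estimated correlation), with CTSS at 1.22 ± 0.092 and MRC1 at 0.84 ± 0.079. The median of this list was 0.084 in males and 0.89 in females. Of 26 endothelial markers 13 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.0145, or 0.837 with estimated correlation), with CDH5 at 0.99 ± 0.10, KDR at 0.61 ± 0.072 and FLT1 at 0.51 ± 0.065. Of 78 ribosomal protein genes 49 fell and 2 rose (51 and 2 adjusted over the list alone; adjusted p = 5.76e-09, or 0.854 with estimated correlation).

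Further liver lists differed on average over both sexes, each more in females by the interaction. T and NK cell markers had 14 higher and 0 lower of 34, 15 and 0 adjusted over the list alone, adjusted p = 0.000892, or 0.849 with estimated correlation. They included CD3G (0.99 ± 0.11), CD3D (0.99 ± 0.13) and GZMA (3.62 ± 0.43), a protease of killer cells. Antigen presentation had 9 higher and 2 lower of 22, 10 and 2 adjusted over the list alone, adjusted p = 0.00271, or 0.837 with estimated correlation. They included BOLA-DRB3 (0.95 ± 0.10) and BOLA-DRA (0.84 ± 0.096). Hepatocyte markers had 12 higher and 3 lower of 26, 14 and 4 adjusted over the list alone, adjusted p = 0.0118, or 0.854 with estimated correlation. They included ALB (0.63 ± 0.082) and RBP4 (0.64 ± 0.097). The unfolded protein list had 13 higher and 5 lower of 29, 14 and 5 adjusted over the list alone, adjusted p = 0.0421, or 0.894 with estimated correlation. They included DNAJB9 (1.05 ± 0.12) and EDEM1 (0.81 ± 0.10). Mitochondrially encoded genes (0 higher and 12 lower of 13, the same adjusted over the list alone, adjusted p = 5.49e-06, or 0.837 with estimated correlation) tested lower on average, with COX3 at -0.78 ± 0.095 and COX1 at -0.52 ± 0.085.

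The difference between origins itself differed between the sexes in 4505 liver genes, 2079 with a more positive and 2426 with a more negative difference in males. CHRD, IMPA1, SETD6, ZNF696 and ATP8B3 led the first group, with male minus female differences of 1.45 ± 0.14, 1.31 ± 0.12, 1.16 ± 0.11, 1.35 ± 0.13 and 1.48 ± 0.15. PROS1 (-1.32 ± 0.12), PPIB (-1.40 ± 0.13), EIF4H (-1.59 ± 0.15) and LAPTM4A (-1.19 ± 0.11) led the second. The hormone gene RLN3 and the ribosyltransferase gene ART1 were at 0 in the 3 independent AI female libraries, and at least 50.9-fold and 68.3-fold higher in IVP females, but both were counted in stand-in library AI female 4. Of 13 mitochondrially encoded genes 12 had a more positive difference in males, the same adjusted over the list alone (adjusted p = 3.10e-15, or 0.730 with estimated correlation). Of 24 macrophage markers 18 had a more negative one (adjusted over the list alone 18, and 1 positive; adjusted p = 1.41e-09, or 0.730 with estimated correlation). The protease inhibitor A2M (-1.74 ± 0.19) and the collagen COL14A1 (-0.88 ± 0.11) did so too. Without the stand-in libraries and their genes, 2504 genes were called.

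Further lists had a more negative difference in males than in females. These were T and NK cell markers (1 more positive and 14 more negative of 34, 1 and 17 adjusted over the list alone, adjusted p = 3.37e-05, or 0.898 with estimated correlation), with PRF1 at -1.71 ± 0.25, and B and plasma cell markers (0 more positive and 6 more negative of 20, 0 and 7 adjusted over the list alone, adjusted p = 0.00913, or 0.898 with estimated correlation), with PAX5, a B cell transcription factor, at -5.17 ± 0.87. Antigen presentation had 0 more positive and 7 more negative of 22, the same adjusted over the list alone, adjusted p = 0.0324, or 0.909 with estimated correlation. They included TAPBP (-0.72 ± 0.15). The interferon response had 0 more positive and 2 more negative of 40, 0 and 0 adjusted over the list alone, adjusted p = 0.0210, or 0.909 with estimated correlation. They included MX2 (-2.76 ± 0.69) and IFIT5 (-0.98 ± 0.31). Hepatocyte markers had 2 more positive and 16 more negative of 26, 2 and 17 adjusted over the list alone, adjusted p = 1.68e-05, or 0.898 with estimated correlation. They included RBP4 (-1.29 ± 0.19) and the fibrinogen chain FGB (-1.04 ± 0.18). The unfolded protein list had 1 more positive and 14 more negative of 29, 1 and 17 adjusted over the list alone, adjusted p = 6.42e-05, or 0.900 with estimated correlation. They included PDIA4 (-2.01 ± 0.32) and CALR (-1.22 ± 0.21). Heat shock genes had 0 more positive and 11 more negative of 24, the same adjusted over the list alone, adjusted p = 0.0162, or 0.909 with estimated correlation. They included HSPB1 (-1.04 ± 0.20). Chromatin genes (9 more positive and 0 more negative of 33, the same adjusted over the list alone, adjusted p = 0.0464, or 0.898 with estimated correlation) tested as more positive in males, with EED (0.67 ± 0.14), HDAC3 (0.65 ± 0.11) and EHMT2 (0.59 ± 0.14), which methylates histones.

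Between the sexes, averaged over both origins, 2256 liver genes differed, 1281 higher and 975 lower in males. XIST, the RNA that coats the inactive X chromosome, was lower in males (adjusted p = 4.51e-18). TDRD9, a helicase of the germ line, stood at 12.3 ± 1.42 and 9.78 ± 1.76 CPM in males and 0.485 ± 0.144 and 0.711 ± 0.681 CPM in females (4.20 ± 0.27). INHBA, a subunit of activin (1.61 ± 0.12), the antimicrobial peptide LEAP2 (0.80 ± 0.075), DEPDC5 (0.63 ± 0.062) and TSC22D1 (0.51 ± 0.050) were higher in males, and TWNK (-0.68 ± 0.060), the mitochondrial helicase, LRRC8B (-0.76 ± 0.079), GK (-0.74 ± 0.079) and GRHPR (-0.70 ± 0.078) lower. Of 23 genes of cholesterol biosynthesis and uptake 19 were higher in males (21 adjusted over the list alone; median 0.83, adjusted p = 3.60e-17, or 0.480 with estimated correlation), among them SQLE (1.24 ± 0.21), FDFT1 (0.97 ± 0.17) and ACAT2 (0.76 ± 0.11). Of 22 lipogenic genes 12 were higher, the same adjusted over the list alone (adjusted p = 2.41e-06, or 0.418 with estimated correlation), with the desaturase SCD at 3.28 ± 0.51.

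Of 36 cell cycle genes 13 were higher and 1 lower in male livers (23 and 3 adjusted over the list alone; adjusted p = 8.54e-06, or 0.627 with estimated correlation), UBE2C (1.28 ± 0.24) and CDC20 (1.58 ± 0.31) among them. Of 29 genes of fatty acid oxidation 9 were lower and 1 higher (13 and 4 adjusted over the list alone; adjusted p = 0.000154, or 0.627 with estimated correlation), with the carnitine transferase CPT1B at -1.21 ± 0.14. The imprinted list (0 higher and 4 lower of 25, 2 and 4 adjusted over the list alone, adjusted p = 6.33e-13, or 8.90e-05 with estimated correlation) tested lower in males. So did the X-linked list (1 higher and 4 lower of 13, 1 and 6 adjusted over the list alone, adjusted p = 8.07e-33, or 8.90e-05 with estimated correlation), and both hold XIST. KDM6A, which escapes X inactivation, stood at -0.47 ± 0.064, EIF2S3 at -0.34 ± 0.072 and the imprinted cell cycle inhibitor CDKN1C at -0.56 ± 0.12. The count was 878 without the stand-in libraries and their genes, 1423 without AI female 4 alone and 1449 without IVP male 2 alone.

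Further lists differed between the sexes in liver. Hepatocyte markers had 7 higher and 0 lower of 26, 9 and 0 adjusted over the list alone, adjusted p = 0.000308, or 0.627 with estimated correlation. They included TTR (0.84 ± 0.086) and ALB (0.49 ± 0.082). The stellate cell, fibroblast and matrix list had 6 higher and 0 lower of 31, 8 and 1 adjusted over the list alone, adjusted p = 0.00146, or 0.627 with estimated correlation. They included TPM2 (0.58 ± 0.10), TAGLN (0.93 ± 0.16) and ACTA2 (0.72 ± 0.16). T and NK cell markers had 7 higher and 0 lower of 34, 10 and 0 adjusted over the list alone, adjusted p = 0.00332, or 0.697 with estimated correlation. They included CD3D (0.60 ± 0.13) and GZMK (1.92 ± 0.47). The unfolded protein and integrated stress list had 4 higher and 0 lower of 29, 10 and 0 adjusted over the list alone, adjusted p = 0.000559, or 0.688 with estimated correlation. They included ATF4 (0.31 ± 0.081) and PSAT1 (0.45 ± 0.11). Immediate early genes had 4 higher and 1 lower of 29, 8 and 1 adjusted over the list alone, adjusted p = 0.0160, or 0.627 with estimated correlation. They included FOSB (0.96 ± 0.23) and JUN (0.36 ± 0.095). Ribosomal protein genes had 10 higher and 0 lower of 78, 13 and 0 adjusted over the list alone, adjusted p = 0.000308, or 0.850 with estimated correlation. They included RPS9 (0.28 ± 0.055). Lower in males were genes of the urea cycle and amino acid breakdown (2 higher and 5 lower of 31, 2 and 8 adjusted over the list alone, adjusted p = 0.0274, or 0.627 with estimated correlation), with TAT at -0.58 ± 0.088 and CTH at -0.58 ± 0.097, and mitochondrially encoded genes (0 higher and 5 lower of 13, 0 and 10 adjusted over the list alone, adjusted p = 1.55e-05, or 0.627 with estimated correlation), with ND4L at -0.47 ± 0.090.

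In the muscle of male calves, 957 of 15682 genes differed, 540 higher and 417 lower in IVP calves, 334 of them by over 2-fold. SPEGNB (Entrez gene 513894) rose from 48.4 ± 5.40 to 128 ± 25.1 CPM (n = 4 in each; 1.40 ± 0.17, adjusted p = 0.00321), and GSTM3, a glutathione transferase, from 19.3 ± 7.73 to 88.6 ± 36.1 CPM (2.20 ± 0.28). SH3BGRL3 (1.21 ± 0.19), the phosphatase PTPN18 (1.67 ± 0.26), CCDC28B (0.97 ± 0.15), NT5C (1.91 ± 0.31), ALG13 (1.36 ± 0.23) and PWWP2A (0.65 ± 0.11) rose as well. ARPP21 (-1.65 ± 0.26), MYT1L (-2.29 ± 0.36), the kinesin KIF6 (-2.49 ± 0.41), SNX33 (-0.86 ± 0.14), the splicing regulator of titin RBM20 (-0.74 ± 0.13), SMG5 (-0.79 ± 0.14) and the muscle nitric oxide synthase NOS1 (-1.10 ± 0.19) fell.

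In muscle males 10 lists passed, 1 of them with fry. Genes of fatty acid oxidation tested lower: 8 of 27 fell, and adjusted over the list alone 17 fell and 1 rose (median -0.61, adjusted p = 4.65e-08, or 0.324 with estimated correlation). ETFDH, which passes electrons to the respiratory chain, went from 62.7 ± 14.8 to 29.8 ± 6.37 CPM (-1.07 ± 0.18), HADHA stood at -0.84 ± 0.17 and CPT1B at -0.97 ± 0.22. Of 26 genes of the growth hormone, IGF and insulin axis 5 fell (7 adjusted over the list alone; adjusted p = 0.00177, or 0.715 with estimated correlation), including the insulin receptor INSR (-0.58 ± 0.16) and its substrates IRS1 (-0.84 ± 0.20) and IRS2 (-0.93 ± 0.25). Of 23 genes of muscle atrophy and proteolysis 3 fell (5 adjusted over the list alone; adjusted p = 0.000320, or 0.788 with estimated correlation), namely the ubiquitin ligase subunits FBXO40 (-0.995 ± 0.18) and FBXO32 (-1.22 ± 0.29) and the autophagy receptor SQSTM1 (-0.51 ± 0.15). The slow fibre gene CSRP3 (-1.59 ± 0.39) fell, alone in its list (0 higher and 1 lower of 17, the same adjusted over the list alone, adjusted p = 0.00102, or 0.788 with estimated correlation). Of structural genes (0 higher and 2 lower of 28, the same adjusted over the list alone, adjusted p = 0.00702, or 0.788 with estimated correlation), MYBPC1 (-0.88 ± 0.22) and ACTN2 (-0.83 ± 0.22) fell. Nuclear genes of oxidative phosphorylation tested lower (2 higher and 6 lower of 78, 4 and 11 adjusted over the list alone, adjusted p = 0.0349, or 0.788 with estimated correlation). SDHA stood at -0.77 ± 0.19, ATP5F1B at -1.59 ± 0.36 and COX6A2 at 0.84 ± 0.17.

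The interferon response tested higher in IVP male muscle: 5 of 39 were called, and adjusted over the list alone 9 rose and 1 fell (median 0.89, adjusted p = 6.07e-05, or 0.788 with estimated correlation). IRF9, a transcription factor of the interferon signal, went from 11.04 ± 2.55 to 24.9 ± 9.22 CPM (1.17 ± 0.26), and DHX58 (1.89 ± 0.47) and IFI6 (3.99 ± 1.03) rose. PSMB10, a subunit of the immunoproteasome, stood at 0.99 ± 0.21 and JCHAIN, the joining chain of immunoglobulins, at 1.22 ± 0.30, the 1 called B and plasma cell marker of 18, the same adjusted over the list alone (adjusted p = 0.0482, or 0.788 with estimated correlation). KLRB1, a receptor of natural killer cells, was at 0 in all 4 AI males and in IVP male 4, and its mean in IVP males, 0.589 CPM, was at least 7.31-fold higher. Of 78 ribosomal protein genes 5 rose, the same adjusted over the list alone (adjusted p = 6.56e-06, or 0.788 with estimated correlation), RPS25 (0.81 ± 0.14), RPS29 (0.92 ± 0.17) and RPL39 (0.67 ± 0.13) first. None of 13 mitochondrially encoded genes was called by edgeR, over all genes or adjusted over the list alone, with COX3 at 0.88 ± 0.31 (median 0.55, adjusted p = 0.0482, or 0.788 with estimated correlation). Their share of counts was highest in IVP male 4 (14.0%).

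Further list members called in male muscle were the fatty acid synthase FASN (0.87 ± 0.16), the sterol enzyme SQLE (1.65 ± 0.31), TSSC4 (0.60 ± 0.13) and PGK1 (-2.37 ± 0.41). The male count, in which AI male 1 and IVP male 1 are not independent, moved with single libraries, from 957 to 1776 without IVP male 1, 147 without IVP male 2, 43 without IVP male 3 and 136 without AI male 1, and to 448 without the stand-in library and genes and 2 by voom. With only the 8 male libraries it was 0 by edgeR (2484 at an unadjusted p under 0.05), and without the stand-in library and with the sets of males as a covariate, which nearly follow origin, 0 by edgeR (1994 at that level), against 1921 by DESeq2 with all libraries.

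In the muscle of female calves, 1270 of 15682 genes differed, 573 higher and 697 lower in IVP calves, 467 by over 2-fold. IGFBP5 (Entrez gene 404185), which binds insulin-like growth factors, rose from 80.7 ± 25.1 CPM (n = 3) to 324 ± 72.7 CPM (n = 4; 2.01 ± 0.25, adjusted p = 0.000737). SMOC2 (1.19 ± 0.15), RGS3 (0.97 ± 0.12), the corepressor TLE1 (1.58 ± 0.20), HDHD3 (1.29 ± 0.17), the cytokine IL1B (2.25 ± 0.30) and the kinase PAK1 (1.16 ± 0.16) rose. The liver gene PROC was at 0 in the 3 independent AI female libraries and at least 28.6-fold higher in IVP females, but was counted in stand-in library AI female 2. PPP1R3E, a glycogen-targeting subunit of protein phosphatase 1 (-1.25 ± 0.14), REV3L (-1.24 ± 0.15), WDR45B (-0.96 ± 0.12), RHOBTB3 (-1.25 ± 0.16), CLEC1A (-2.16 ± 0.28), PM20D2 (-1.56 ± 0.21), ACSL4 (-1.44 ± 0.20) and GPR19 (-1.10 ± 0.15) fell.

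Genes of muscle atrophy and proteolysis tested lower in IVP female muscle, 9 of 23 and 10 adjusted over the list alone (median -0.39, adjusted p = 1.67e-07, or 0.323 with estimated correlation). TRIM63, a ubiquitin ligase of the sarcomere, went from 778 ± 437 to 204 ± 13.9 CPM (-1.93 ± 0.27), against 208 ± 44.0 and 121 ± 21.5 CPM in AI and IVP males. FBXO32 (-1.84 ± 0.30), FBXO30 (-2.46 ± 0.35), GABARAPL1 (-1.95 ± 0.28), and SESN1 of the insulin list (-1.14 ± 0.20) fell as well. Structural genes tested higher, 9 of 28 and 12 adjusted over the list alone (adjusted p = 1.67e-07, or 0.323 with estimated correlation). ACTA1, skeletal muscle actin, stood at 1.14 ± 0.23 and the creatine kinase CKM at 0.62 ± 0.15. Of 17 fast fibre genes 7 rose, and adjusted over the list alone 10 rose and 1 fell (adjusted p = 9.99e-07, or 0.410 with estimated correlation), with MYL1 at 0.72 ± 0.18, MYBPC2 at 0.77 ± 0.19 and PVALB at 2.86 ± 0.71. Their median was 0.66, and that of slow fibre genes 0.66 (adjusted p = 0.0810). Of myogenic genes (1 higher and 0 lower of 25, 4 and 1 adjusted over the list alone, adjusted p = 0.00631, or 0.323 with estimated correlation), the acetylcholine receptor gene CHRNA1 (1.19 ± 0.28) rose.

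Genes of glycolysis and glycogen tested higher in IVP female muscle, with 3 of 31 called and 4 adjusted over the list alone (adjusted p = 0.000952, or 0.410 with estimated correlation). PPP1R3C, another glycogen-targeting subunit, stood at 2.07 ± 0.30 and PGAM2 at 0.81 ± 0.23. Of 15 gluconeogenic genes PC (1.43 ± 0.25) and SLC37A4 (0.68 ± 0.14) rose, 2 adjusted over the list alone (adjusted p = 0.00978, or 0.323 with estimated correlation). Imprinted genes tested higher, 4 of 26 and 8 adjusted over the list alone (adjusted p = 0.00948, or 0.410 with estimated correlation), with MEST at 1.75 ± 0.25, SNRPN at 0.76 ± 0.15 and NDN at 0.73 ± 0.16. Of 28 immediate early genes 5 rose and 3 fell (11 and 5 adjusted over the list alone; adjusted p = 0.0140, or 0.697 with estimated correlation). The nuclear receptors NR4A1 (2.09 ± 0.40), NR4A2 (2.26 ± 0.43) and NR4A3 (2.68 ± 0.46) rose and FOSL2 (-1.60 ± 0.28) fell. Of 23 endothelial markers 4 rose, the same adjusted over the list alone (adjusted p = 0.00314, or 0.529 with estimated correlation), with CDH5 at 0.68 ± 0.20 and RAMP2 at 0.69 ± 0.21. Ribosomal protein genes (3 higher and 0 lower of 78, 1 and 0 adjusted over the list alone, adjusted p = 1.75e-08, or 0.529 with estimated correlation) had a median of 0.23, with RPL39 at 0.58 ± 0.13. Nuclear genes of oxidative phosphorylation (1 higher and 0 lower of 78, 0 and 0 adjusted over the list alone, adjusted p = 1.67e-07, or 0.507 with estimated correlation) had a median of 0.21, with UQCR11 at 0.56 ± 0.17. AI females were also the muscle group with the lowest share of counts in the 10 most abundant genes.

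Other lists also tested higher in female muscle. The stellate cell, fibroblast and matrix list had 2 higher and 0 lower of 31, 1 and 0 adjusted over the list alone, adjusted p = 0.00427, or 0.584 with estimated correlation. They included SPARC (0.59 ± 0.18) and MYL9 (1.45 ± 0.29). Antigen presentation had 1 higher and 0 lower of 22, the same adjusted over the list alone, adjusted p = 0.00796, or 0.529 with estimated correlation. They included BOLA-DMA (0.77 ± 0.21). In the interferon response (0 higher and 0 lower of 39, the same adjusted over the list alone, adjusted p = 0.00948, or 0.735 with estimated correlation) edgeR called no gene, and SAMD9 stood at 1.39 ± 0.50 and IFIH1 at 0.98 ± 0.38.

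Among other list members LHPP (0.87 ± 0.17) rose and LTF (-2.001 ± 0.35) fell. The female count was 406 without the stand-in library and its genes, 254 without the stand-in library and with the sets of males as a covariate, 3176 with only the 8 female libraries, 5818 by voom and 1922 by DESeq2. Leaving out IVP female 1, 2 or 4 gave 676, 775 and 461, and leaving out AI female 1, 2 or 4 gave 692, 434 and 478.

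**Figure D3:**
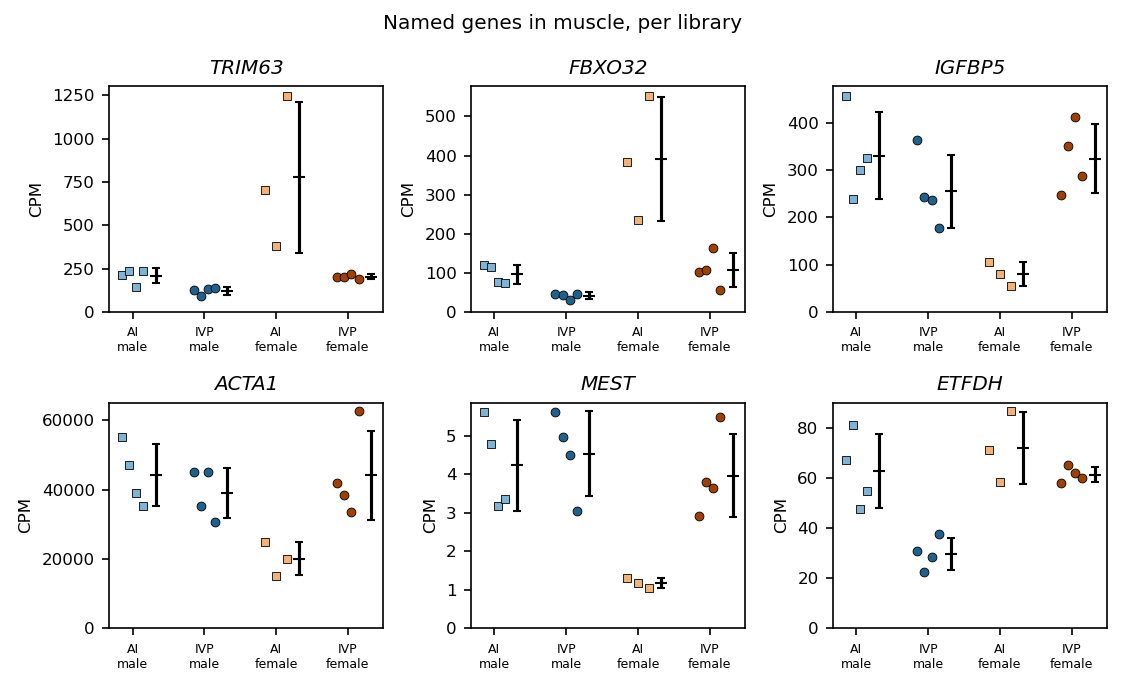
Levels of TRIM63, FBXO32, IGFBP5, ACTA1, MEST and ETFDH in muscle (CPM, vertical axis) by origin and sex (horizontal axis), with 1 point per independent library and a black bar for the mean ± SD. TRIM63 stands at 778 ± 437 CPM in AI females, where its libraries spread widely, and at 204 ± 13.9 in IVP females.

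Averaged over both sexes, 1804 muscle genes differed, 890 higher and 914 lower in IVP calves. SPEGNB (0.97 ± 0.12), CCDC28B (0.85 ± 0.11), NIPSNAP1 (1.13 ± 0.15), the mitochondrial citrate carrier SLC25A1 (1.004 ± 0.14), SH3BGRL3 (0.92 ± 0.13) and PTMA (0.65 ± 0.093) rose. DHX32 (-1.02 ± 0.13), the kinase STK38L (-0.78 ± 0.11), TRIM63 (-1.35 ± 0.18), CHD1L (-1.26 ± 0.17), FBXO32 (-1.53 ± 0.21) and PM20D2 (-1.06 ± 0.15) fell. Atrophy genes tested lower (0 higher and 12 lower of 23, 0 and 15 adjusted over the list alone, adjusted p = 1.61e-09, or 0.476 with estimated correlation). Interferon genes tested higher (6 higher and 0 lower of 39, 19 and 0 adjusted over the list alone, adjusted p = 7.24e-06, or 0.815 with estimated correlation), with the antiviral gene OAS2 at 1.78 ± 0.45. Genes of the insulin axis tested lower (2 higher and 9 lower of 26, 4 and 10 adjusted over the list alone, adjusted p = 0.0144, or 0.722 with estimated correlation), with SESN1 at -0.85 ± 0.14. Imprinted genes tested higher (7 higher and 1 lower of 26, 8 and 1 adjusted over the list alone, adjusted p = 0.0102, or 0.722 with estimated correlation), with NDN at 0.66 ± 0.11 and CDKN1C at 0.87 ± 0.18. Hepatocyte markers had a median log2 difference of 1.51 (2 higher and 0 lower of 22, 1 and 0 adjusted over the list alone, adjusted p = 0.0392, or 0.815 with estimated correlation). ITIH1 rose by 3.10 ± 0.72 from levels near 0, and ALB counts were highest in IVP male 3 (4192) and IVP female 3 (2916). Without the stand-in library and its genes 895 genes were called, without the stand-in library and with the sets of males as a covariate 66, and without IVP female 1 or 4, or AI female 1, 2 or 4, 1156, 1010, 1134, 917 and 974.

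Ribosomal protein genes tested higher over both sexes in muscle (15 higher and 0 lower of 78, 33 and 0 adjusted over the list alone, adjusted p = 4.08e-12, or 0.772 with estimated correlation), with RPL39 at 0.62 ± 0.093. Genes of fatty acid oxidation tested lower (0 higher and 4 lower of 27, 0 and 5 adjusted over the list alone, adjusted p = 0.00567, or 0.722 with estimated correlation), with medians of -0.61 in males and 0.10 in females. Antigen presentation had 4 higher and 0 lower of 22, the same adjusted over the list alone, adjusted p = 0.0145, or 0.815 with estimated correlation. They included B2M (0.77 ± 0.17) and PSMB8 (0.63 ± 0.17). B and plasma cell markers had 2 higher and 0 lower of 18, the same adjusted over the list alone, adjusted p = 0.0188, or 0.815 with estimated correlation. They included JCHAIN (0.80 ± 0.21). Fast fibre genes had 5 higher and 1 lower of 17, 6 and 2 adjusted over the list alone, adjusted p = 0.0188, or 0.815 with estimated correlation. They included TNNT3 (0.60 ± 0.17) and TNNI2 (0.60 ± 0.17). Myogenic genes had 2 higher and 1 lower of 25, the same adjusted over the list alone, adjusted p = 0.0188, or 0.534 with estimated correlation. They included ACTC1 (0.71 ± 0.20) and MYL4 (1.10 ± 0.32). Endothelial markers had 3 higher and 0 lower of 23, the same adjusted over the list alone, adjusted p = 0.0145, or 0.815 with estimated correlation. They included PLVAP (0.98 ± 0.19). The stellate cell, fibroblast and matrix list had 3 higher and 0 lower of 31, the same adjusted over the list alone, adjusted p = 0.0145, or 0.815 with estimated correlation.

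The difference between origins differed between the sexes in 433 muscle genes, 263 more positive and 170 more negative in males. SLC25A37 (1.70 ± 0.25), WDR45B (1.13 ± 0.17), SRSF11 (1.11 ± 0.17), CLEC1A (2.51 ± 0.39), the kinase ABL1 (1.84 ± 0.30) and PPP1R3E (1.20 ± 0.20) were more positive in males. IGFBP5 (-2.38 ± 0.35), PGP (-1.48 ± 0.21), STBD1 (-2.13 ± 0.31), CNTFR (-1.47 ± 0.22), SHROOM3 (-2.94 ± 0.45) and TMCC2 (-1.88 ± 0.29) were more negative. Of 27 genes of fatty acid oxidation 1, HADHA (-1.04 ± 0.24), had a more negative difference in males (13 adjusted over the list alone; adjusted p = 1.72e-06, or 0.261 with estimated correlation), and of 28 structural genes 1, ACTA1 (-1.32 ± 0.32; 13 adjusted over the list alone; adjusted p = 2.79e-10, or 0.246 with estimated correlation). Gluconeogenic genes had 2 of 15 (6 adjusted over the list alone; adjusted p = 0.000182, or 0.101 with estimated correlation), PGK1 (-3.20 ± 0.56) and MDH2 (-0.85 ± 0.19). Without the stand-in library and its genes 68 were called, by voom 767, by DESeq2 1207, and without the stand-in library and with the sets of males as a covariate 0 by edgeR (1806 at an unadjusted p under 0.05). The count was 1061 without IVP male 1, 215, 158 and 156 without IVP male 2, IVP male 3 and AI male 1, 190, 225, 233 and 152 without IVP females 1 to 4, and 193, 64, 239 and 134 without AI females 1 to 4.

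Other metabolic and fibre lists had a more negative difference in males. Glycolysis and glycogen had 0 more positive and 2 more negative of 31, 0 and 5 adjusted over the list alone, adjusted p = 1.11e-05, or 0.279 with estimated correlation. They included PPP1R3C (-2.45 ± 0.42). Immediate early genes had 2 more positive and 4 more negative of 28, 3 and 8 adjusted over the list alone, adjusted p = 0.000384, or 0.575 with estimated correlation. They included NR4A1 (-2.99 ± 0.55), NR4A2 (-3.38 ± 0.60) and NR4A3 (-3.54 ± 0.68). No member was called by edgeR in 5 further lists, whose leading genes missed the threshold. These were nuclear genes of oxidative phosphorylation (0 more positive and 0 more negative of 78, 0 and 13 adjusted over the list alone, adjusted p = 2.25e-09, or 0.447 with estimated correlation; SDHA -0.98 ± 0.27), fast fibre genes (0 more positive and 0 more negative of 17, 0 and 6 adjusted over the list alone, adjusted p = 7.17e-06, or 0.447 with estimated correlation; MYH1 -1.18 ± 0.34), slow fibre genes (0 more positive and 0 more negative of 17, the same adjusted over the list alone, adjusted p = 3.44e-05, or 0.451 with estimated correlation; LMCD1 -1.52 ± 0.48) and heat shock genes (0 more positive and 0 more negative of 23, the same adjusted over the list alone, adjusted p = 0.0154, or 0.796 with estimated correlation; DNAJB4 -1.27 ± 0.44). The 5th list, of mitochondrially encoded genes, tested as more positive in males (0 more positive and 0 more negative of 13, the same adjusted over the list alone, adjusted p = 0.0246, or 0.901 with estimated correlation), with COX3 at 1.001 ± 0.44.

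Between the sexes, averaged over both origins, 2968 muscle genes differed, 1577 higher and 1391 lower in males. XIST was lower in males (adjusted p = 3.11e-06). TDRD9 (4.47 ± 0.30), the collagen COL27A1 (1.35 ± 0.12), the helicase DDX11 (1.12 ± 0.12), DMPK (1.000 ± 0.12), the kinase of myotonic dystrophy, and RGS3 (0.72 ± 0.086) were higher in males. The mitochondrial carrier SLC25A33 (-2.23 ± 0.20), ARID5B (-2.25 ± 0.24), the adiponectin receptor ADIPOR2 (-0.82 ± 0.090) and NAMPT (-1.48 ± 0.17), an enzyme of NAD synthesis, were lower. Of 23 atrophy genes 15 were lower in males (16 adjusted over the list alone; median -0.70, adjusted p = 1.14e-12, or 0.109 with estimated correlation), with FBXO32 at -1.68 ± 0.21 and PSMD11 at -0.73 ± 0.10. Of 20 glucocorticoid response genes 7 were lower and 1 higher (10 and 3 adjusted over the list alone; adjusted p = 0.00119, or 0.371 with estimated correlation), FKBP5 at -1.16 ± 0.20 and TSC22D3 at -0.60 ± 0.092. The X-linked list tested lower in males (0 higher and 6 lower of 13, 1 and 6 adjusted over the list alone, adjusted p = 1.10e-06, or 0.0135 with estimated correlation), with KDM6A at -0.87 ± 0.10 and TXLNG at -1.02 ± 0.15. Imprinted genes (9 higher and 1 lower of 26, 14 and 3 adjusted over the list alone, adjusted p = 0.0283, or 0.505 with estimated correlation) tested higher with a median of 0.40, while their mean was -0.11 with XIST in the list. The imprinted growth regulator DLK1 stood at 1.26 ± 0.21. The count was 1953 without the stand-in library and its genes, 1938 without AI female 2 alone, 35 without the stand-in library and with the sets of males as a covariate and 1628 without the 2 libraries highest in ALB.

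Further lists passed between the sexes in muscle. Ribosomal protein genes had 23 higher and 0 lower of 78, 32 and 0 adjusted over the list alone, adjusted p = 5.59e-09, or 0.604 with estimated correlation. They included RPL36 (0.55 ± 0.11) and RPLP1 (0.45 ± 0.096). Nuclear genes of oxidative phosphorylation had 17 higher and 2 lower of 78, 20 and 2 adjusted over the list alone, adjusted p = 0.00119, or 0.8003 with estimated correlation. They included COX6A2 (0.64 ± 0.12) and ATP5MG (0.47 ± 0.086). Antigen presentation had 9 higher and 0 lower of 22, 11 and 0 adjusted over the list alone, adjusted p = 0.00127, or 0.505 with estimated correlation. They included BOLA-DMB (0.92 ± 0.19). The interferon response had 5 higher and 0 lower of 39, the same adjusted over the list alone, adjusted p = 0.000521, or 0.8003 with estimated correlation. They included GBP4 (1.51 ± 0.35) and ZBP1 (1.88 ± 0.53). The matrix list had 7 higher and 0 lower of 31, 8 and 0 adjusted over the list alone, adjusted p = 0.00115, or 0.604 with estimated correlation. They included the collagen COL5A1 (0.69 ± 0.15). Endothelial markers had 7 higher and 0 lower of 23, the same adjusted over the list alone, adjusted p = 0.00119, or 0.604 with estimated correlation. They included STAB1 (0.70 ± 0.17) and ENG (0.60 ± 0.15). Cholangiocyte markers had 3 higher and 0 lower of 8, the same adjusted over the list alone, adjusted p = 0.0283, or 0.247 with estimated correlation. They included PROM1 (1.41 ± 0.27). Nerve and Schwann cell markers had 3 higher and 0 lower of 14, 6 and 0 adjusted over the list alone, adjusted p = 0.0375, or 0.505 with estimated correlation. They included the myelin gene PRX (1.152 ± 0.36). Genes of fatty acid oxidation tested lower in males (0 higher and 7 lower of 27, 0 and 12 adjusted over the list alone, adjusted p = 6.79e-05, or 0.371 with estimated correlation), with PDK4, which spares glucose, at -3.15 ± 0.55. So did circadian clock genes (1 higher and 6 lower of 19, 3 and 8 adjusted over the list alone, adjusted p = 0.0300, or 0.439 with estimated correlation), with PER1 at -0.65 ± 0.15 and TEF at -0.45 ± 0.10.

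**Figure D4:**
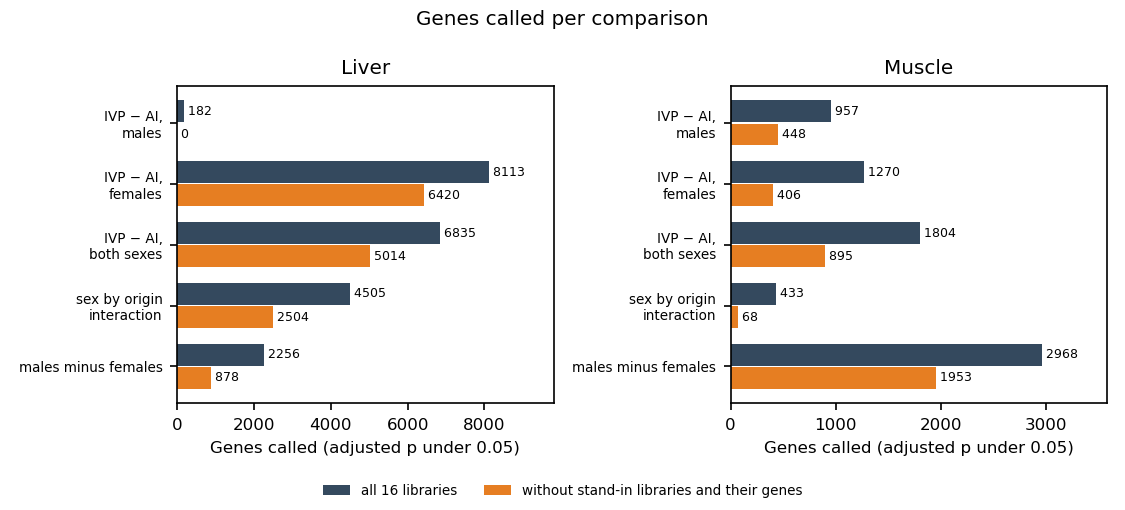
Number of genes called (horizontal axis) for each contrast (vertical axis) in liver and muscle, with all 16 libraries and without the stand-in libraries and the genes counted only there. In liver females 8113 and 6420 genes were called, in liver males 182 and 0.

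In liver, 125 genes were called in the same direction in both sexes (86 higher and 39 lower in IVP calves), against 42.9 for independent lists, and 10 in opposite directions. Across genes, which are not independent replicates, the log2 differences of the sexes had a Pearson r of 0.057 and a Spearman rho of 0.256. In muscle, 76 genes were shared in direction (39 higher and 37 lower) against 38.3, and 20 were opposite, with r = 0.165 and rho = 0.147. Between tissues, males shared 1 gene in direction against 5.10 for independent lists, and 13 were opposite (r = -0.0066, rho = -0.157). Females shared 353 against 291.6, with 235 opposite (r = 0.076, rho = 0.071). Overlaps that include males rest on calls that fell from 182 to 1 in liver without IVP male 2 and from 957 to 43 in muscle without IVP male 3. Liver and muscle came from the same calves, so differences between single calves enter both tissues.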

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

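The tests of the stand-in libraries, of the size of the liver difference, of other splits in liver with all libraries, of other splits in muscle males and females with all libraries, and of splits without the stand-in libraries in comparisons other than females were chosen only after the result was seen. A stand-in library lies at the mean of its own group only in the real split, which favours that split in advance. Counts with all libraries therefore do not exclude chance where a stand-in library is compared, although 1 split, the real one, gave as many genes in each. In liver, males had 182 genes against at most 7 for the other splits, females 8113 against 2, both sexes 6835 against 0, the interaction 4505 against 1 and the sexes 2256 against 10. In muscle, females had 1270 against 19, both sexes 1804 against 1, the interaction 433 against 0 and the sexes 2968 against 750.

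Without the stand-in libraries and their genes, liver females had 6420 genes against 3027, for the split that parts IVP females 2, 3 and 4 from the rest, both sexes 5014 against 9, the interaction 2504 against 401 and the sexes 878 against 5. Muscle females had 406 against 3. In each of these 1 split, the real one, gave as many. An adjustment could favour the real split, so none of these excludes chance. Interaction counts also came from the splits of origin, and sex splits mix AI females with other calves. In liver males 0 genes were left by edgeR (1653 at an unadjusted p under 0.05) against 14, so 35 of 35 splits give as many and the test decides nothing.

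In muscle, AI male 1 and IVP male 1 deviate from their groups together (correlation 0.902), where the next of 84 pairs from different groups had 0.487. They are the 2 males that the set found in the counts exchanges. They are not independent, so splits that move them do not exclude chance: males had 957 against 2065 with all libraries and 448 against 1591 without the stand-in library (2 of 35 splits as many in both), both sexes 895 against 1, the interaction 68 against 1 and the sexes 1953 against 33. Without these 2 males as well, both sexes had 819 against 13, the interaction 162 against 34 and the sexes 3656 against 1839. In each 1 split, the real one, gave as many, but chance is not excluded, for the same reasons. The males then left differ in origin and in set alike, so the set stays open as a cause. An adjustment that used the groups could favour the real split in both tissues.

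The liver difference between origins differed between the sexes for many named genes, by the interaction test. Male minus female log2 differences are given, first for genes with the larger difference in females. Among genes leading in females these were PROS1 (-1.32), EIF4H (-1.59), LAPTM4A (-1.19), SCCPDH (-0.91), NPC2 (-1.18), PPIB (-1.40), SERBP1 (-0.83) and PSAP (-2.23) for genes that rose, and FAM193B (0.92), SETD6 (1.16), ATP8B3 (1.48), CHRD (1.45), KIF23 (1.41), ATP2C2 (0.89), WWP2 (1.01) and TOP3A (0.76) for genes that fell. Macrophage genes were CTSS (-1.45), C1QC (-1.72), C1QA (-1.38) and MRC1 (-0.80). Genes of T and NK cells and antigen presentation were CD3D (-1.72), CD3G (-1.25), PRF1 (-1.71), BOLA-DRB3 (-1.04), BOLA-DRA (-0.87) and BOLA-DMA (-0.53). Hepatocyte genes were RBP4 (-1.29), ALB (-0.77) and PLG (-0.71). Genes of protein folding were DNAJB9 (-1.46), EDEM1 (-1.2), DNAJC3 (-0.58), HSPD1 (-0.95), HSP90AA1 (-1.01) and DNAJA1 (-0.99). Mitochondrially encoded genes were COX2 (1.19), COX3 (1.52) and ND1 (1.52), ribosomal protein genes RPLP0 (-1.14), RPS28 (0.71), RPL38 (1.01) and RPS13 (0.66), and nuclear genes of oxidative phosphorylation ATP5F1B (-1.05), ATP5ME (0.90) and NDUFB10 (0.36). Others were CDH5 (-1.33), IGFBP3 (-0.84), IL6R (-0.93) and NGFR (-0.40). Among genes leading in males, SULT1B1 (-0.71), MMP14 (-1.40), SPPL2A (-0.50), CAVIN2 (-0.81), RTN4 (-0.75) and AOC3 (-0.58) differed in the same way. The difference was larger in males for BOLA-DOB (-0.75), MYT1L (-1.75), RABEPK (-0.50) and ALPK2 (-6.20), the last a fitted value against a group at 0. The B cell gene SPIB (-2.18) went in opposite directions, lower in IVP males and higher in IVP females.

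List medians of the male minus female difference in liver were 0.16 for chromatin genes, -0.80 for the interferon response, -0.49 for antigen presentation, -0.60 for T and NK cells, -0.67 for B and plasma cells and -0.79 for macrophages. They were -0.55 for hepatocytes, -0.78 for the unfolded protein response, -0.34 for heat shock genes and 1.19 for mitochondrially encoded genes.

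The larger liver difference in females was weighed against 3 technical explanations. Without the stand-in libraries and their genes 6420 genes were called in females, and with all libraries thinned to the smallest total 7970, which argues against both as the whole cause. Fewer hepatocytes in IVP females would lower their genes, but the median of the hepatocyte list was 0.5454 higher. A biological difference between the sexes in how conception in vitro acts stays open as a hypothesis. So does a biological or technical difference of the few AI females from other calves, as RNA quality and batch were not tested. The adjustment before deposit may also have shrunk the spread within groups, which would raise all of these counts.

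The 3 stand-in libraries were weighed next. A pool or repeat of the group's RNA would carry counting noise of its own. The highest squared distance among these libraries was 0.08165 times that noise, but an adjustment could give this whatever was sequenced. An adjustment of the counts between sets of libraries would leave genes at 0 in a whole set as they were, and even values were in excess there by at least 41.24 percentage points, against at most 3.55 when the genes' values were dealt to other genes. In liver males, liver females and muscle females the set so found was the stand-in library alone, and the next set had an excess of 34.0 to 44.1, so its members are not certain. No label names such a step, and no biological explanation was tested.

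In muscle the difference between origins also differed between the sexes. Genes leading in males were GSTM3 (2.14), NT5C (2.02), ALG13 (1.74), PWWP2A (0.79), ARPP21 (-1.62) and SMG5 (-0.76), with the list members PGK1 (-3.20), FBXO40 (-0.98), FASN (1.10), HADHA (-1.04) and KLRB1 (8.80), the last a fitted value against a group at 0. Genes leading in females were SMOC2 (-1.01), IGFBP5 (-2.38), RGS3 (-0.81), TLE1 (-1.68), HDHD3 (-0.97), IL1B (-2.27) and PAK1 (-0.99) for genes that rose and PPP1R3E (1.20), REV3L (1.07), WDR45B (1.13), RHOBTB3 (1.01) and CLEC1A (2.51) for genes that fell. List members were GABARAPL1 (1.77) and FBXO30 (1.90) of atrophy, NR4A1 (-2.99), NR4A2 (-3.38) and NR4A3 (-3.54) of immediate early genes, ACTA1 (-1.32) and CHRNA1 (-1.54) of muscle structure and myogenesis, and MEST (-1.65), PPP1R3C (-2.45), LTF (2.32) and BOLA-DMB (-1.48) of other lists. List medians were -0.70 for fatty acid oxidation, -0.75 for gluconeogenesis, -0.44 for glycolysis, -0.60 for structural genes, -1.47 for slow and -0.63 for fast fibre genes. They were -0.31 for heat shock genes, -0.88 for immediate early genes, -0.33 for nuclear genes of oxidative phosphorylation and 0.73 for mitochondrially encoded genes.

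Single libraries lay far from the other 3 of their group in 17 of the 255 groups of 4 tested, where chance gives about 12.75. In liver these were ADAMTS1 in AI male 1 (14.9 CPM, others 11.7 to 12.02), SCCPDH in IVP female 2 (68.8 CPM, others 61.1 to 61.7), and IGFBP3 (319.9 CPM, others 264 to 269.5) and RPL38 (126 CPM, others 90.0 to 95.5) in IVP female 1. In muscle of IVP males they were SPEGNB (90.5 CPM, others 137 to 145) and IRF9 (11.1 CPM, others 29.1 to 29.9) in library 1, MYT1L in library 3 (0.499 CPM, others 1.05 to 1.2), and INSR (69.1 CPM, others 51.0 to 52.7), COX3 (15110 CPM, others 5666 to 7016) and ND6 (2390 CPM, others 659 to 804) in library 4. In muscle of AI males they were PTPN18 in library 2 (2.02 CPM, others 1.146 to 1.29), IFI6 (8.97 CPM, others 1.44 to 2.30) and JCHAIN (5.46 CPM, others 2.43 to 2.82) in library 3 and TSSC4 in library 4 (21.8 CPM, others 15.4 to 15.96). In muscle of IVP females they were FOSL2 (42.2 CPM, others 29.8 to 31.9) and IFI6 (33.4 CPM, others 3.35 to 5.45) in library 3 and PPP1R3E in library 4 (6.53 CPM, others 8.55 to 8.59).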

How the results depend on the processing

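The alternatives without the stand-in libraries, without their genes, with thinned counts, without the stand-in library and with the sets of males as a covariate, and without the 2 muscle libraries highest in ALB were chosen only after the result was seen. Counts of changed genes in liver females and in liver over both sexes stayed within 1.5 times under all alternatives run, leave-one-out included. The cause was not tested for the values below, except that fewer libraries or genes entered where the setting says so.

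In liver males (182 genes), no filter gave 113, the likelihood ratio test 461, voom 3027, DESeq2 627, age as a covariate 369, only the 8 libraries compared 4, and leaving out the stand-in libraries 1, or 0 by edgeR with their genes (1653 at an unadjusted p under 0.05). The liver interaction (4505) gave 8118 by voom, and 2630 and 2504 without the stand-in libraries and also without their genes. The liver sexes (2256) gave 6083, 856 and 878 in the same order.

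In muscle males (957), no filter gave 636, the likelihood ratio test 1577, voom 2, DESeq2 1921, 1 surrogate variable 1674, only the 8 libraries compared 0 by edgeR (2484 at an unadjusted p under 0.05), leaving out the stand-in library 436 and also its genes 448, leaving it out with the sets of males as a covariate 0 by edgeR (1994 at that level) and leaving out the 2 libraries highest in ALB 2. Muscle females (1270) gave 5818 by voom, 1922 by DESeq2, 3176 with only the 8 libraries, 434 and 406 without the stand-in library and its genes, and 254 without it and with the covariate. The sets of males nearly follow origin, so the covariate takes away most of that contrast. Muscle over both sexes (1804) gave 917, 895 and 66 for the last 3 settings. The muscle interaction (433) gave 270 with no filter, 1032 by the likelihood ratio test, 767 by voom, 1207 by DESeq2, 1190 with a surrogate variable, 64 and 68 without the stand-in library and its genes, 0 by edgeR without it and with the covariate (1806 at an unadjusted p under 0.05) and 103 without the 2 libraries highest in ALB. The muscle sexes (2968) gave 1938, 1953, 35 and 1628 for the last 4.

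Leaving out each library in turn gave 1 to 214 genes in liver males, 7046 to 7965 in females, 6015 to 6911 over both sexes, 3534 to 4727 for the interaction and 1423 to 2488 between the sexes. In muscle it gave 43 to 1776, 434 to 1016, 917 to 2252, 64 to 1061 and 1938 to 3715, in the same order. With the replicate block, liver had 194, 8126, 6832, 4581 and 2326 genes and muscle 1033, 1121, 1788, 444 and 2982, and 108 list tests passed. The labels do not say that the replicate numbers pair calves. Correlations of such pairs ran from -0.377 to 0.432 in liver and from -0.284 to 0.170 in muscle, except for 0.902 between IVP male 1 and AI male 1. In all, 12 of 18 and 5 of 21 were over 0.1, and the own number gave the highest correlation in 21 of 42 and 12 of 45 comparisons of a library with another group.

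Genes called in both sexes in the same direction numbered 588 in liver (125 at the adjusted threshold) and 186 in muscle (76) at an unadjusted p under 0.01, against 215.0 and 107.0 for independent lists. Both tissues of males shared 30 genes (1) in direction against 54.5, with 103 opposite. Of 105 list tests, 3 passed with an estimated correlation, 63 with fry, 101 with age as a covariate and 104 without the stand-in libraries. For single named genes no direction reversed in the settings that follow. The side of the threshold was the same, gained and lost for 452, 15 and 9 with a surrogate variable, 441, 33 and 1 by DESeq2, 400, 28 and 48 by voom, 114, 10 and 71 with only the 8 libraries, 396, 0 and 80 without the stand-in libraries and 102, 0 and 156 without the stand-in library and with the covariate. The call of imprinted genes, muscle sex (median 0.4007), was lost without the 2 libraries highest in ALB. The direction of the list test was reversed there (adjusted p = 0.9105), with a median of 0.3846. In simulated counts 4-fold changes were mostly called at the depth of these libraries, while 1.5-fold changes in muscle were mostly missed.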

Other observations

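No test in this part was chosen only after its result was seen, but the genes singled out here were chosen after their values were seen. In liver females the log2 differences were 2.68 for MMP14, a matrix protease, 1.55 for CAVIN2, a coat protein of caveolae, and 1.28 for RTN4, against 1.28, 0.74 and 0.53 in males. Without the stand-in library the male differences were 1.28, 0.74 and 0.53 (adjusted p = 0.106 each), with fewer libraries tested. In muscle, FBXO32 fell in both sexes, with log2 differences of -1.22 ± 0.29 in males and -1.84 ± 0.30 in females.

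Hepatocyte transcripts were found in muscle libraries, with ALB counts of 4192 in IVP male 3 and 2916 in IVP female 3. The hepatocyte list reached 0.309% of its liver level in the first and 0.162% in the second, and 0.0117% to 0.0649% in the other muscle libraries. Liver RNA in these libraries is a candidate explanation: across the list, the lower Spearman correlation with the liver library of the same calf number was 0.8022. It was up to 0.7805 in other muscle libraries, so it hardly sets these apart. Of the detected list members, 11.54% (3 of 26) were counted in AI female 2 and in no other library of its group. That library is not among these 2, so this mark says nothing about them. No biological explanation was tested.

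In muscle the mitochondrially encoded share of counts was 14.0% in IVP male 4, 4.13% to 5.24% in the other IVP males and 1.59% to 7.19% in AI males.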
